A study of Salmo salar with 36 samples.

How the data were processed

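RNA of 36 whole Atlantic salmon fry was measured on 36 two-colour oligonucleotide microarrays of the cGRASP salmonid design, 1 fry per array. The fry came from 6 cross types with 6 fish each. Per the labels' protocols, the RNA of each fry was amplified and labelled with Cy5, and a common reference, a pool of amplified RNA from all 36 fry, was labelled with Cy3 and hybridised to every array. No dyes were swapped, so a dye effect of a probe is shared by all arrays and cancels between cross types. Because the reference holds the RNA of the same fry, the log ratios of different fish can oppose each other: 5 of the 630 pairs of fish correlated under -0.3 over all complete probes, the lowest at -0.36, and the direction given by the dye labels was kept.

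The deposited scanner files hold intensities that were not normalised. Per the file headers, spots were quantified with ImaGene 9.0, which gave a median signal and a median local background per spot and channel, with flags for empty, poor, saturated and manually rejected spots. Per the file headers, the empty-spot threshold was 2. The deposited value table holds log2 ratios made by the authors, and the submitters' processing notes name R 3.6.1; the exact steps and the rule for empty cells are not given in the sources used here. Set against the scanner values, each deposited column correlated at 0.963 to 0.999 with the log2 ratio of background-subtracted median signals. Its direction is therefore fish over reference, while a correlation does not show the base of the logarithm. The medians of the deposited columns lay between -0.15 and 0.07, and how they were centred is unknown. Every filled cell of the table came from an unflagged spot, and 12828 of the 43689 probes had any value there.

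From the scanner intensities, background was corrected with normexp and an offset of 50, log2 ratios were normalised within each array by loess, and control spots had weight 0 in the loess. Spots with a manual flag, or with a poor-spot flag and no saturated channel, were left out (0.346% to 8.42% of spots per array), while saturated spots were kept. A probe was tested when its Cy5 spot was not flagged empty on at least 6 arrays and it had at least 3 values in every cross type. This kept 42980 of 43689 probes, so the filter removed little. On the median array 77.1% of the negative-control spots were also not flagged empty, which means that passing the filter does not show that a transcript was present. A stricter filter, chosen after the data were seen, asked for a Cy5 signal above the 95th percentile of the array's 153 negative-control spots on 6 arrays and left 33973 probes.

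All arrays entered 1 limma fit (version 3.58.1, in R 4.3.3) of 6 means, without covariates, and 13 contrasts were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment per contrast at 0.05. A moderated F-test over all 6 cross types was adjusted in the same way. The median residual SD per probe was 0.446 on the log2 scale. The contrasts, the filter, the alternatives and the rule for naming genes were fixed before the data were examined. The rule was to name, of the probes with a gene name that passed the test, the 8 largest rises and the 8 largest falls in each comparison of Farm.NA, Farm.EO and Wild, the 5 largest each way elsewhere, and all where fewer than 5 passed, with the 3 smallest p-values. No gene could be named by it from the sources used here. The files give 19956 probes a cluster identifier and 23324 a clone-like identifier or no name. Of the 409 probes with a sequence accession, 0 matched the salmon gene table of assembly Ssal_v3.1. Those accessions name sequence records, which could not be looked up in the sources used here. Without gene names the 26 gene lists fixed in advance were not tested, and probes are given by their position on the array and their cluster, at most 2 that rose and 2 that fell per comparison. All probes named here were called, or had the smallest p of their comparison, and were picked after their values were seen.

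The design holds 3 families of each cross type with 2 fish of each family. The labels do not say which fish share a family, so fish were treated as independent and the p-values over fish may be too small. The arrays lay on 9 slides of 4, as the image names in the headers show, and each slide held 2 or 4 cross types. The slide was used as a fixed block in 1 alternative, and values within slides are given beside the results. The other alternatives were no background correction, median centring in place of loess, no filter, the compared cross types alone, the fish number as a block, the deposited values, array weights, and leaving out each fish in turn. Chosen after the data were seen were the stricter filter, the probes of the deposited table alone, leaving out Wild fish 4 and Farm.EO fish 4, and leaving out a saturated spot of 1 named probe and the spots at background of 2 others. The fitting code was tested on simulated data with 200 changed probes. At a log2 change of 1 in Farm.EO versus Wild, 52% of 50 changed probes were recovered among 42980, against 4% at 0.5, 90% at 1.5 and 94% at 2, with 8 false calls. The simulated noise was normal and independent between probes, and it held no slide effect and no far fish. Recovery in the real data may therefore be lower. The number of arrays limits the precision. No 2 fish of a cross type had near-identical arrays; the highest correlation was 0.492.

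A held-out score placed each fish on a scale with the training fish of Farm.NA at -1 and those of Farm.EO at 1. For each fish, the 200 probes with the largest moderated statistics between the 2 farm strains were chosen without that fish, leaving out 2 probes described in the report, and the fish's distance between the strain means was averaged over them.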

Results

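Gene expression was compared among whole fry of 6 Atlantic salmon cross types, with 6 individual fish in each and 1 array per fish. The 3 pure types were Farm.NA, a farm strain of North American origin, Farm.EO, a farm strain of Norwegian origin, and Wild, a population from a Newfoundland river. The 3 first-generation hybrids were Hyb.NAff (Farm.NA mother, Wild father), Hyb.EOwf (Wild mother, Farm.EO father) and Hyb.EOff (Farm.EO mother, Wild father). Values are log2 ratios of a fish against a pool of all 36 fish, and means are given with the SD over fish. The median Cy5 signal per array ranged from 111.5 to 802 intensity units, and 42.3% to 95.7% of probes were above background in the fish channel. The number of arrays limits the precision of every comparison. The probes named here carry cluster or clone identifiers, and what their transcripts encode is not given in the sources used here.

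The first question was whether the North American farm strain differed from the wild population. Probe C188R069 (CLUSTER_ID#5420991) was high in Farm.NA, at 0.98 ± 0.46 (SD, n = 6), and low in Wild, at -2.74 ± 0.55 (SD, n = 6), a 13.2-fold difference. Probe C060R108 (CLUSTER_ID#5404626) was 11.6-fold higher, at 0.37 ± 0.59 (SD, n = 6) in Farm.NA and -3.17 ± 0.54 (SD, n = 6) in Wild. The Cy5 spot of C060R108 was saturated in 1 of 6 Farm.NA fish, and without that fish the difference was 10.7-fold (6.81-fold against Farm.EO). Probe C216R062 (CLUSTER_ID#5628867) was 3.12-fold lower in Farm.NA, at -1.18 ± 0.30 (SD, n = 6) against 0.46 ± 0.49 (SD, n = 6). At C216R062 4 of 6 Farm.NA fish were above background, and with those 4 alone it was 3.11-fold lower. These were the 3 probes of 42980 called by limma. Their log2 differences were 3.72 (SE 0.40, adjusted p = 1.1e-06), 3.54 (SE 0.36, adjusted p = 5.2e-07) and -1.64 (SE 0.26, adjusted p = 0.0031). At both of the first probes each Farm.NA fish lay above each Wild fish, and all 6 fish of both cross types were above background. On the median array 77.1% of the negative-control spots were too, so this does not show that the low Wild values are signal. On the 2 slides that held both cross types, the differences were 3.83 and 3.83 at C188R069, 2.96 and 2.91 at C060R108, and -1.81 and -1.64 at C216R062. With the slide as a block the 3 calls held (3.73, 3.36 and -1.64). The size of the difference at C216R062 did not shrink, but it was not past the threshold, with median centring (-1.76, adjusted p = 0.89), in the authors' deposited values (-1.73, 0.14) or in a fit of the compared cross types alone (-1.64, 0.078). Over the 23 alternatives its adjusted p ranged from 0.00075 to 0.89. At an unadjusted p under 0.05 there were 3732 probes, where chance gives 2149.

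**Figure D1:**
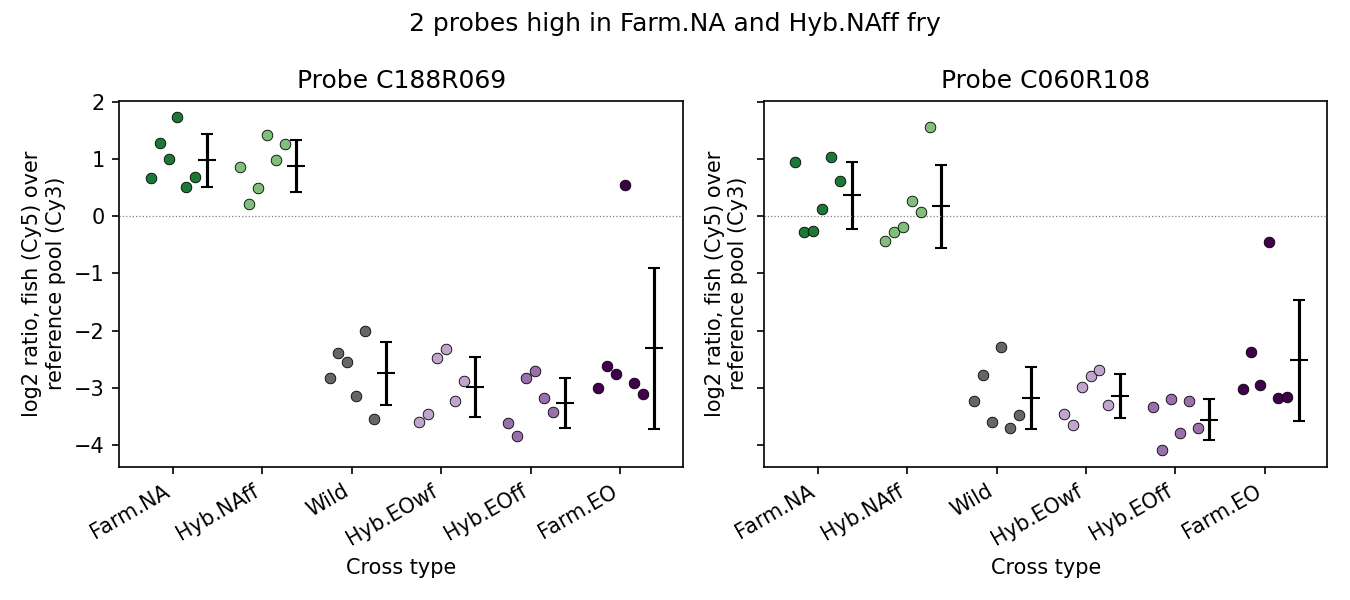
Log2 ratio of each fish (Cy5) over the reference pool (Cy3) at probes C188R069 and C060R108, by cross type; points are single fish, ticks and bars are the mean and SD of 6 fish. All 12 Farm.NA and Hyb.NAff fish lie at -0.43 or above, and the other cross types lie at -2.0 or below except for Farm.EO fish 4, at 0.55 and -0.45.

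The same question for the European farm strain gave no called probe. The smallest p in Farm.EO versus Wild belonged to probe C206R001, with a log2 difference of 2.96 (SE 0.53, adjusted p = 0.13). C188R069 was at -2.31 ± 1.41 (SD, n = 6) in Farm.EO, and C060R108 at -2.52 ± 1.05 (SD, n = 6). Neither differed from Wild, with adjusted p of 0.96 and 0.93 in limma. By limma 2276 probes had an unadjusted p under 0.05, against 2149 by chance. The number of called probes, 0 with all fish, depended on single fish. It was 29 without Wild fish 4 and 13 without Farm.EO fish 4, and 16 (4 higher, 12 lower) with array weights. Leaving out both of those fish, a step added after the data were seen, gave 68 called probes, 17 higher and 51 lower in Farm.EO. With the slide as a block 1 probe was higher and 1 lower.

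The 2 farm strains were compared directly. Farm.EO fry had lower levels than Farm.NA fry at C188R069, by 9.78-fold, and at C060R108, by 7.39-fold. They had higher levels at C174R128 (CLUSTER_ID#5615076), at 0.67 ± 0.80 (SD, n = 5) against -1.17 ± 0.32 (SD, n = 6), and at C212R025 (CLUSTER_ID#5678511_327bp_2_clones), at 0.60 ± 0.75 (SD, n = 6) against -0.85 ± 0.41 (SD, n = 6). The log2 differences were -3.29 (SE 0.40, adjusted p = 4e-05 in limma), -2.89 (SE 0.36, adjusted p = 4e-05), 1.84 (SE 0.33, adjusted p = 0.035) and 1.45 (SE 0.27, adjusted p = 0.045). At C212R025 5 of 6 Farm.NA fish were above background, and with those 5 alone the log2 difference was 1.37. No other probe passed, and 3874 had an unadjusted p under 0.05. Within the slides that held both strains the differences ran from -4.73 to -0.14 at C188R069 on 3 slides, -3.41 to -1.07 at C060R108 on 3, 1.57 to 1.68 at C174R128 on 2 and 0.34 to 1.28 at C212R025 on 3. With the slide as a block the 2 lower probes stayed past the threshold (-3.27 and -2.76) and the 2 higher ones did not (adjusted p = 0.17 for both). The size of the latter hardly moved, at 1.82 (SE 0.37) for C174R128 and 1.42 (SE 0.31) for C212R025, while the SE grew. The 2 higher probes lost the call in 13 and 14 of 23 alternatives, with adjusted p from 0.00091 to 0.38 and from 0.0011 to 0.45. The 2 lower ones lost it only in a fit of the 2 strains alone (adjusted p = 0.26 for both), where no probe was called; their adjusted p ranged from 3.2e-11 to 0.26 and from 9.4e-09 to 0.26 over the alternatives.

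Fish 4 of Farm.EO stood apart from its cross type in this comparison. It was at 0.55 at C188R069 and -0.45 at C060R108, where the other 5 Farm.EO fish lay between -3.11 and -2.62 and between -3.17 and -2.37. On the held-out score between the farm strains it lay at -1.14, and the other 5 lay between 0.33 and 1.10. Wild fish 4, on the same slide, lay at 1.34, above the other 5 Wild fish at -0.58 to 0.04. Without Farm.EO fish 4 the number of probes called between the farm strains was 180. Without both fish it was 278, of which 174 were higher and 104 lower in Farm.EO, and all 4 probes of the full comparison were among them. Both fish were chosen for their distance from their cross types, which by itself raises such counts.

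**Figure D2:**
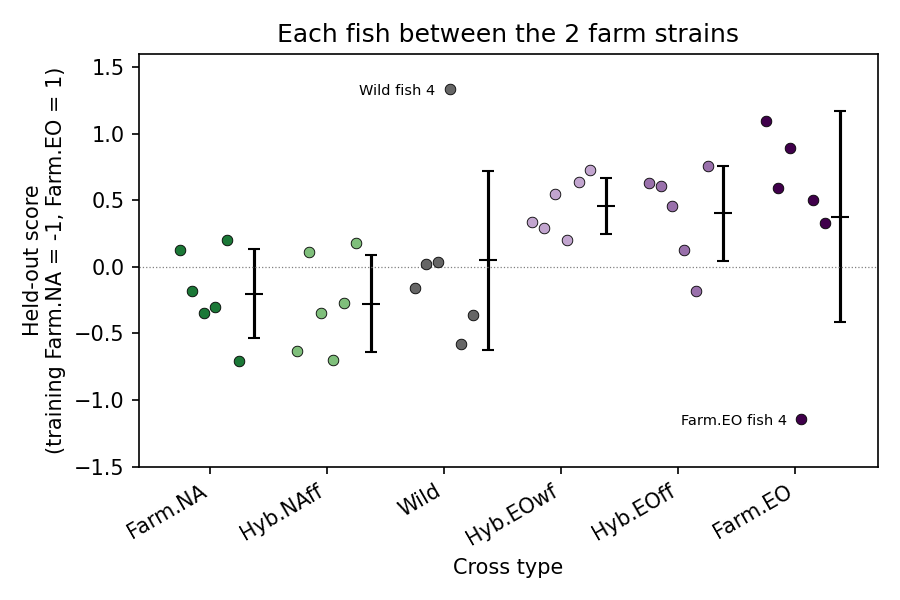
Held-out score of each fish between the 2 farm strains (no unit; the scale is set by the fish that choose the probes, with Farm.NA at -1 and Farm.EO at 1), by cross type; points are single fish, ticks and bars are the mean and SD of 6 fish. Wild fish 4 at 1.34 and Farm.EO fish 4 at -1.14 lie apart from the rest of their cross types.

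The overlap of the farm strains' differences from Wild was examined next. No probe could be called in both comparisons, since none was called in Farm.EO versus Wild, so the called probes cannot show an overlap or its absence. Across probes, which are not independent replicates, the log2 differences correlated at r = 0.364. Both share the Wild arrays, and unchanged groups simulated with a shared, simulated Wild group gave 0.50 on average (0.486 to 0.511 in 100 simulations). Each probe was drawn independently there, while real probes can vary together. That range is therefore too narrow to show whether 0.364 is unusual. The covariance was 0.0389, against 0.0406 in the simulations. With Wild split into 2 sets of 3 fish the correlation averaged -0.03, from -0.30 to 0.205 over 20 divisions.

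In the North American hybrid, the question was how fry of a Farm.NA mother and a Wild father compared with both parent types. Hyb.NAff fry were high at the same 2 probes as Farm.NA, at 0.87 ± 0.46 (SD, n = 6) for C188R069 and 0.17 ± 0.73 (SD, n = 6) for C060R108. Against Wild these were 12.2-fold and 10.1-fold higher (log2 differences 3.61, SE 0.40, and 3.34, SE 0.36; adjusted p = 2.3e-06 for both in limma), and no other probe was called. On the 3 slides that held both cross types the differences ran from 3.33 to 4.40 and from 3.04 to 3.85, and with the slide as a block they were 3.62 and 3.13. At an unadjusted p under 0.05 there were 1881 probes. Against Farm.NA no probe was called and 1736 had an unadjusted p under 0.05. The difference from Farm.NA was -0.11 (SE 0.40) at C188R069 and -0.20 (SE 0.36) at C060R108. C216R062, low in Farm.NA, was at 0.08 ± 0.58 (SD, n = 6) in Hyb.NAff, with a log2 difference of 1.26 from Farm.NA (adjusted p = 0.36). Against the mean of the parent types no probe was called by limma (1233 with an unadjusted p under 0.05). The smallest p-values were those of C188R069, 1.75 above the mid-parent (SE 0.35), and C060R108, 1.57 above it (SE 0.31), each with adjusted p = 0.30. The mid-parent is the mean of the parents' log2 values. Where the parents differ many-fold, it lies below the log2 of their average level. A hybrid at that average level would also lie above the mid-parent, so part of these differences needs no departure from the average. Without Wild fish 4 and Farm.EO fish 4 both probes were called, at 1.71 (SE 0.23) and 1.66 (SE 0.24). Farm.EO fish 4 is not in this comparison. It enters only the shared estimate of the spread, and it lay far from its cross type at these 2 probes. The count stayed 0 in 26 of 29 alternatives, among them all 18 that left out 1 fish of the compared cross types.

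The European hybrids of both directions of cross were compared with their parent types and with each other, which asks whether the mother's origin mattered. No probe was called by limma in any of these comparisons. C188R069 and C060R108 were low in both hybrids, at -2.99 ± 0.52 and -3.14 ± 0.38 in Hyb.EOwf (SD, n = 6) and at -3.26 ± 0.44 and -3.55 ± 0.36 in Hyb.EOff (SD, n = 6). For Hyb.EOwf versus Wild 2614 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.46, at C189R085 with a log2 difference of 0.87 (SE 0.17). For Hyb.EOff versus Wild there were 2625, and C064R152 had the smallest adjusted p, 0.12, with a log2 difference of -1.26 (SE 0.22). Versus Farm.EO the counts were 2203 in Hyb.EOwf and 1295 in Hyb.EOff, with smallest adjusted p of 0.56 and 1. Between the reciprocal hybrids 1565 probes had an unadjusted p under 0.05, fewer than the 2149 given by chance, and the smallest adjusted p was 1. Against the mid-parent the counts were 2407 in Hyb.EOwf and 1792 in Hyb.EOff, with smallest adjusted p of 0.14 and 0.87. Without Wild fish 4 and Farm.EO fish 4, 5 probes were called in Hyb.EOwf versus Wild (2 higher, 3 lower), 6 in Hyb.EOff versus Wild, all lower, and 2 in Hyb.EOff versus Farm.EO, both higher. Without Wild fish 4 alone, 6 were called in Hyb.EOff versus Wild. The planned test of a lean of the hybrids towards the mother's side needed 10 probes called in a fit of Farm.EO and Wild alone. That fit called 0, and the test was not run.

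Over all 6 cross types, the moderated F-test of limma called 22 probes, and 3430 had an unadjusted p under 0.05. In 15 of the 22 the means of Farm.NA and Hyb.NAff both lay above those of Hyb.EOwf, Hyb.EOff and Farm.EO, and in 5 both lay below. Random orders of the means would put 20% of probes in these 2 classes, which were chosen after the values were seen. The Wild mean lay nearer the 3 cross types with a European parent in 14 of these 20 probes and nearer Farm.NA and Hyb.NAff in 6. C099R013 (CLUSTER_ID#5615768), for example, was at 0.88 in Farm.NA and 0.80 in Hyb.NAff, at -0.12 in Wild, and at -1.02, -0.61 and -0.48 in Hyb.EOwf, Hyb.EOff and Farm.EO (adjusted p = 0.0046). C222R131 (CLUSTER_ID#5622989) ran the other way, at -1.28 and -1.42 in Farm.NA and Hyb.NAff, -0.39 in Wild, and 0.50, 0.13 and 0.14 in the other 3 cross types (adjusted p = 0.0046). With the slide as a block 3 probes passed the F-test. Leaving out single fish gave 6 to 164, the latter without Farm.EO fish 4, and leaving out both fish described above gave 361.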

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

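The tests of slide, swap, label, array quality, sequence variant and mid-parent in this part were chosen after the results were seen, and those of other divisions of the fish were set down before they were run; the shuffles within slides were added last. Of 66 groups of 6 values examined for a far value (5 called probes, 2 scores and 4 array measures in each cross type), 9 held one, and about 3.3 would by chance.

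Farm.EO fish 4 lay far above the other 5 Farm.EO fish at C188R069 (0.55, others -3.11 to -2.62) and C060R108 (-0.45, others -3.17 to -2.37), and far below them on the held-out score between the farm strains (-1.14, others 0.33 to 1.10). Wild fish 4 lay far above the other Wild fish on that score (1.34, others -0.58 to 0.04). An exchange of the 2 fish is argued against, because at C060R108 Farm.EO fish 4, at -0.45, would have to lie with the other 5 Wild fish, and all Wild fish lay between -3.69 and -2.29. An effect that moves all arrays of the shared slide the same way is argued against as well. Farm.EO fish 4 shifted by -1.73 and Wild fish 4 by 1.5 from the median score of their cross types. An effect that differs among the arrays of that slide was not tested. Array quality stays open for Farm.EO fish 4: 0 of 10 values of the 2 arrays (signal, background, share above background, spread and share of spots left out) lay outside the range of the other 34, but 8.02% of its spots were left out, rank 2 of 36. A single wrong label of Farm.EO fish 4 may be a candidate explanation and cannot be told apart from variation among fish. At C188R069 its value of 0.55 lay inside the Farm.NA and Hyb.NAff range of 0.21 to 1.73, at C060R108 it lay just below their lowest value of -0.43, and no Farm.NA or Hyb.NAff fish was low at these probes as a partner would be.

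The 2 probes high in all 12 Farm.NA and Hyb.NAff fish form the next pattern. The slide as its cause is argued against, because with the slide as a block the smaller of the 2 differences between Farm.NA and Wild was still 3.36. A sequence variant under the probe stays open and cannot be told apart from a difference in RNA level, since the probe sequences are not used here. The 2 probes correlated at r = 0.944 over 36 fish, which mostly restates the 2 levels, and whether they lie on 1 transcript is not known. Both cross types had Farm.NA mothers, and no hybrid with a Farm.NA father was measured. The mother's side and the strain therefore cannot be told apart at these probes. Expression of Hyb.NAff above the mid-parent also stays open, since both probes were picked as high in Hyb.NAff and the limma test over all probes gave an adjusted p of 0.30 for each. The mid-parent of log2 values also lies below the average level of parents that differ this much.

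At 4 probes the difference from Wild was not the same in Farm.EO as in Farm.NA, by the direct test of the farm strains. C174R128 and C212R025 among them lost the call with the slide as a block (adjusted p = 0.17 for both in limma). In a fit of the farm strains alone no probe was called. Hyb.NAff fish 6 had a high value at C060R108 (1.56, others -0.43 to 0.27). Wild fish 5 had a high median Cy5 signal (802, others 197.5 to 393) and background (363, others 1 to 103). Hyb.NAff fish 2 had a high Cy5 background (198.5, others 1 to 27) and few probes above background (42.25%, others 79.4% to 93.5%).

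Other divisions of the same fish, 100 per comparison with the real one included, show how often chance gives as many called probes. For Hyb.NAff versus Wild 1 division (the real one, with 2 called) gave as many, with at most 1 elsewhere. For Farm.EO versus Farm.NA 2 did (real 4), and the highest other, 9, exchanged Farm.EO fish 4 with Farm.NA fish 3. As many calls are therefore rare by chance, as far as divisions that ignore the slide and the families can show. The counts were 2 for both with the slide as a block, and in a fit of the 2 farm strains alone it was 0 for Farm.EO versus Farm.NA. For the F-test 3 did (real 22, highest other 119), which is rare too. Many comparisons were tested in this way, so the divisions do not exclude chance for counts reached by 2 or 3 of them. These divisions ignore the slide, and the one with 119 put all 4 fish of slide 1 in 1 set. The F-test called 3 probes with the slide as a block. When cross types were shuffled within slides, 1 of 100 shuffles, the real one, gave 22, and the highest other gave 1. For Farm.NA versus Wild 9 did (real 3, highest other 34), so chance is not excluded for the count, although it says nothing on the size of single probes. In the remaining 10 comparisons the real count was 0 and all 100 gave as many; the highest others were 291 for Hyb.NAff versus Farm.NA, 200 for the Hyb.EOff mid-parent and 50 for the Hyb.EOwf mid-parent, and 1 to 8 elsewhere. The large counts may reflect a structure of the samples other than cross type, which was not tested. The division with 291 put all 4 fish of slides 6 and 8 on 1 side and all fish of slides 3, 4 and 5 on the other, but it split slides 1 and 2. That with 200 put all 4 fish of slide 9 together and kept the compared fish of slides 6, 7 and 8 in 1 set each, but split slides 4 and 5. That with 50 kept the compared fish of slides 3, 4 and 5 in 1 set each, but split slides 7, 8 and 9. With the slide as a block the real count stayed 0 in Hyb.NAff versus Farm.NA and in both European mid-parent comparisons.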

How the results depend on the processing

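The alternatives were planned, except the stricter filter, the probes of the deposited table the removal of Wild fish 4 and Farm.EO fish 4 and that of the saturated spot of C060R108 and of the spots of C216R062 and C212R025 at background, chosen after the data were seen. C188R069 and C060R108 kept their direction everywhere and their calls against Wild in 23 of 23 alternatives. No named probe reversed. Counts of called probes within 1.5 times of the main one are not repeated, and the cause of a moved count was not tested unless stated. The planned filter removed few probes, so dropping it tests little. Without the filter or with the stricter one, no count moved beyond 1.5 times of the main one.

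No background correction gave 5 calls (2 higher, 3 lower) for Farm.NA versus Wild and 1 for Hyb.EOff versus Wild. Median centring gave 2 for Hyb.EOff versus Wild and 13 in the F-test. The slide as a block gave 2 for Farm.EO versus Wild, 2 for Farm.EO versus Farm.NA, 1 for the Hyb.NAff mid-parent and 3 in the F-test. The deposited values gave 19 (13 higher, 6 lower) for Farm.EO versus Farm.NA and 35 in the F-test, over 12731 probes. The probes of that table with the values used here gave 7 for Farm.NA versus Wild and 39 in the F-test, where fewer probes were adjusted for. Array weights gave 16 for Farm.EO versus Wild, 29 (22 higher, 7 lower) for Farm.EO versus Farm.NA, 1 for Hyb.EOff versus Wild, 2 for the Hyb.EOwf mid-parent and 130 in the F-test. The compared cross types alone gave 0 for Farm.EO versus Farm.NA and 1 for the Hyb.NAff mid-parent. Without Wild fish 4 and Farm.EO fish 4 the counts were 6, 68 and 278 for Farm.NA versus Wild, Farm.EO versus Wild and Farm.EO versus Farm.NA, then 5 and 6 for Hyb.EOwf and Hyb.EOff versus Wild, 2 for Hyb.EOff versus Farm.EO, 2 for the Hyb.NAff mid-parent and 361 in the F-test.

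Leaving out 1 fish gave 3 to 7 calls for Farm.NA versus Wild (7 without Farm.NA fish 5), 0 to 29 for Farm.EO versus Wild, 2 to 180 for Farm.EO versus Farm.NA, 0 to 3 for Hyb.NAff versus Farm.NA (3 without Farm.NA fish 5), 0 to 6 for Hyb.EOff versus Wild, 0 to 1 for the Hyb.EOwf mid-parent (1 without Wild fish 6) and 6 to 164 in the F-test. The highest values came without Wild fish 4 or Farm.EO fish 4 where no other fish is named.

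The fish numbers do not pair the fish. Same-numbered fish of different cross types had a mean correlation of deviations of 0.0061, from -0.136 to 0.188 over pairs of cross types, and 7 of 36 fish correlated best with their own number. The fish number as a replicate block gave 5 calls for Farm.NA versus Wild, 2 for Farm.EO versus Farm.NA and 13 in the F-test. Fish of 1 slide correlated at 0.093 and of different slides at -0.0103. Dim signal limits many probes: 42.3% to 95.7% were above background in the fish channel. The gene list tests were not run, nor were their alternatives. The maternal lean was run only without Wild fish 4 and Farm.EO fish 4, and not under the other settings.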

Other observations

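The division of cross types in the first 2 paragraphs was chosen after the F-test was seen. The slide test and the test of the European mothers were also chosen after, when other scores had already placed Hyb.EOwf on the European side, while the counts of other divisions and of shuffles within slides were set down before they were run. Cross types with a European parent (Hyb.EOwf, Hyb.EOff, Farm.EO) were compared with those without one (Farm.NA, Hyb.NAff, Wild). The comparison uses 18 fish a side, so its count cannot be set against those of pairs of cross types. With equal weight per cross type and all 36 fish, limma called 315 probes, 110 higher and 205 lower with European parentage, with log2 differences from -2.56 to 1.75 and a median size of 0.818. The strongest falls, at C188R069 (-2.56) and C060R108 (-2.19), are the differences of Farm.NA and Hyb.NAff already described, with Wild at the level of the European types. Over the 315 probes the Wild mean lay nearer Farm.NA and Hyb.NAff in 220 and nearer the European types in 95, although probes were called with Wild on the former side, which favours this. C222R131 was higher by 1.29 (adjusted p = 4e-04) and C220R141 (CLUSTER_ID#5651061) by 1.43 (adjusted p = 0.0014). The other 9 divisions of 6 cross types into 3 and 3 gave at most 15. Among 100 divisions of the fish, the real one alone reached 315 and the highest other gave 3, so such a count is rare for fish placed at random. The real division was picked after the F-test and the random ones were not, so chance is not excluded. Fish of 1 family are not independent, which this does not cover either. The authors' deposited values gave 376 of 12731 probes, against at most 14 for other divisions.

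A division of Farm.NA and Hyb.NAff against all other cross types was not counted, so European and Farm.NA parentage are not told apart. A difference by European ancestry may be shared by both hybrids and the farm strain, only as a hypothesis (315 called probes). The slide as its whole cause is argued against: with the slide as a block the median size over the 315 probes was 0.764 (median SE 0.187, against 0.818 and 0.179 without it), and all 315 kept their sign. The count fell to 34 (highest other division 8), of which 32 were among the 315. When cross types were shuffled within slides, the real one alone of 100 gave as many as 315, and the highest other gave 1. Leaving out 1 fish gave 181 (without Farm.EO fish 1) to 824 (without Farm.EO fish 4). Leaving out Wild fish 4 and Farm.EO fish 4 gave 1633, with at most 90 for other divisions. Both fish were chosen for lying far from their cross types on the held-out score between the farm strains. That choice by itself raises the count of this division, and it shapes the means without these fish given below. Eggs of European mothers alone would put Hyb.EOwf, which had Wild mothers, with the cross types without a European parent. Eggs of Farm.NA mothers are not told apart, since both Farm.NA and Hyb.NAff had them. With probes chosen on the other 5 cross types, the 6 Hyb.EOwf fish had a mean score of 0.53 ± 0.45 (SD) on a scale from -1 to 1. Of these, 5 of 6 lay on the European side (exact sign-flip permutation p = 0.0625, not past 0.05). The scores lean against eggs of European mothers as the whole cause but do not settle it. In the same test all 6 Hyb.EOff fish and 5 of 6 Farm.EO fish (exact p = 0.438; without Farm.EO fish 4, at -1.85, 5 of 5 with a mean of 0.84 ± 0.36 (SD), exact p = 0.0625) lay on the European side, and 0 of 6 Farm.NA and 0 of 6 Hyb.NAff fish did. Wild was not placed, with a mean of 0.03 ± 0.89 (SD) and 2 of 6 fish on the European side (exact p = 0.969). That mean rests on Wild fish 4, at 1.74: the other 5 averaged -0.32 ± 0.34 (SD), with 1 of 5 on the European side (exact sign-flip permutation p = 0.125, where 5 fish cannot go below 0.0625). The side of Wild is therefore left open.

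A lean of the European hybrids towards the mother's side was tested without Wild fish 4 and Farm.EO fish 4, a setting chosen after the data were seen, while the test itself was fixed before. In that fit of Farm.EO and Wild alone 24 probes were called. Hyb.EOff had a mean score of 0.42 ± 0.22 (SD, n = 6) and Hyb.EOwf 0.51 ± 0.36 (SD, n = 6), and an exact two-sided permutation test over all assignments gave p = 0.671. No maternal lean was detected.

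The first principal component of the complete probes held 20.1% of the variance. Cross type accounted for 0.222 of its variance and slide for 0.413.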
